A study of Homo sapiens with 10 samples.

How the data were processed

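Chromatin immunoprecipitation, ChIP-bisulfite sequencing and RNA sequencing of the hESC line HUES64 and its derivatives were deposited as 10 processed samples. Per the labels' protocols, cells were grown on mouse feeder cells and then without feeders on matrigel, and endoderm was made with Activin A (100 ng/mL), WNT3A (50 ng/mL) and 0.5% FBS. Hepatoblasts were made from day 5 endoderm with FGF2 (10 ng/mL) and BMP4 (20 ng/mL) and collected at day 10. Cells for ChIP were collected by FACS, per the labels' protocols, and the protocol text used here does not say whether the cells for RNA were sorted too.

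Each peak list gives positions and a score that the authors deposited without a stated unit. Its minimum of 50 is what the peak caller MACS, named in the deposited peak names, writes for 10 times the negative log10 of a p of 1e-05, and the score was read as that. Peaks were called per sample, since each deposited list has its own numbering. The peak caller's version, control sample and filters are not given in the sources used here. The deposited bisulfite files give methylated and total read counts per CpG as text, and a score equal to 1000 times the methylated share. Only CpGs with at least 1 read are listed, and which aligner was used, duplicate removal and strand handling are not given in the sources used here. The hepatoblast values are FPKM with an interval, per the file headers in the layout of Cufflinks, and the label says that replicates 1 and 2 were combined. Of the genes, 71 are marked as having low data, and 79 have an FPKM outside their own interval. Per the submitters' processing notes, TopHat2 2.0.6, Bowtie 0.12.7, BWA 0.5.7, TopHat, Cufflinks and Cuffdiff were used on hg19 or GRCh37, without saying for which data type. Coordinates are printed 1-based on that build as deposited.

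The deposited names of the FOXA2 peak lists call them ChIP-bisulfite lists and give each the same sample number as the bisulfite library of the same replicate number. List 1 and library 1, and list 2 and library 2, may therefore come from the same chromatin or the same reads, and whether peaks were called on bisulfite-converted reads is not stated. As a check of this pairing, reads per listed CpG inside peaks of replicate 1 alone exceeded those of the flanks 1.34-fold in library 1 and 1.05-fold in library 2. Inside peaks of replicate 2 alone the ratios were 0.995 and 1.28. The replicate numbers were therefore taken as pairing FOXA2 lists with bisulfite libraries. For the hESC factors nothing ties the numbers of different factors together.

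Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Peaks on contigs outside the 24 chromosomes and 18 genes on such contigs were left out. Lists overlap where peaks share at least 1 bp. Consensus peaks of FOXA2, SOX2 and NANOG are the merged union of peaks that overlap a peak of the other replicate, and POU5F1 has 1 list. Chance overlap came from 1000 circular shifts within chromosomes, with the one-sided p as 1 plus the shifts as large, over 1 plus the number of shifts, and shares at locus edges were set against 200 shifts. Shares of peaks carry 95% exact (Clopper-Pearson) binomial intervals over peaks, which neighbour each other and are not independent.

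Methylation was taken per library from CpGs with at least 5 reads, as a mean over CpGs in peaks with at least 3 such CpGs. Flanks reached from 1 to 5 kb from either peak end, outside every FOXA2 peak. Sign-flip permutations over peaks (two-sided, 100000 resamples, exact where at most 12 peaks entered) tested the difference, and 10000 resamples were used for alternatives. Peaks below 20% were called low and above 80% high. Median coverage of 1 read per CpG left few peaks for this test, so pooled reads were added as an alternative, with at least 10 reads per peak and, where flanks enter, 10 in the flanks. Read counts of peaks, flanks and libraries are coverage summed over CpGs, so a read that covers several CpGs is counted at each of them. Single CpGs were compared between the libraries with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment.

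A gene was called bound where a consensus peak lay within 10 kb of its locus in the FPKM table. Loci there carry no strand, so a locus edge is within 1 kb of either end. Expression was compared as log2(FPKM + 1) with 10000 random lists, matched on decile of locus length for bound genes and unmatched for fixed lists. Peaks at fixed lists were tested with two-sided Fisher's exact tests against all other genes and adjusted over lists and factors. The 15 lists, fixed before the data were examined, were pluripotency, definitive endoderm, hepatoblast and hepatocyte, pancreas, intestine, lung and thyroid, mesoderm and heart, ectoderm and neural, trophoblast, fibroblast and mesenchyme, endothelium and blood, epithelium, DNA methylation machinery, WNT, NODAL, BMP and FGF signalling, and housekeeping. All of their 192 genes were in the table. HAND1, CDX2 and DNMT3B are each on 2 lists.

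Genes named in the text were members of these lists, the genes nearest to the 10 FOXA2 consensus peaks with the highest mean score and to the 10 POU5F1-SOX2-NANOG peaks with the highest mean rank, the 10 FOXA2-bound genes with the highest FPKM, the genes nearest to the 5 most and 5 least methylated FOXA2 peaks with at least 5 CpGs at 10 reads or more in both libraries, and the 5 genes with most FOXA2 peaks. Only 8 peaks met the methylation rule, so its highest and lowest groups shared peaks. This rule, the main tests and the alternatives were fixed before the data were examined, except those said to have been chosen later.

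The steps were tested on simulated data. For 43109 FOXA2 replicate 1 peaks with 30% planted matches, 31.5% were found overlapping, with 2.94% by shift, and random peaks gave 1.02-fold. Overlap calls against a direct comparison were wrong in 0 of 400. A planted difference of -30 points between peaks and flanks was recovered as -31.0 over 41 peaks in library 1 and -30.6 over 8 in library 2 at 5 reads per CpG. With pooled reads it was -29.8 over 4706 peaks and -29.9 over 1985. Without a planted difference the 4 values lay between -0.13 and 2.16 points. Of 200 CpGs changed from 5% to 95% among 27209, 41.5% were called, with 2 unchanged CpGs called, so the per-CpG test at this coverage misses many large differences. A list of 500 genes raised by 1 on the log2 scale was recovered at 0.91, and one not raised at -0.04, among 22238 genes.

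Alternatives tried were stricter scores of at least 100, reciprocal overlap of 50%, local shifts, equal numbers of top peaks, lists left out in turn, unions, other coverage minimums, read-weighted levels, other CpG minimums, other flanks, other class limits, other peak-to-gene distances, a pseudocount of 0.1 and an FPKM filter of 0.1. Sequence motifs in peaks were not analysed here.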

Results

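HUES64, a human embryonic stem cell (hESC) line, was profiled before and after differentiation in 10 samples that fall into 6 groups. POU5F1 (OCT4), SOX2 and NANOG were mapped by chromatin immunoprecipitation (ChIP) in hESC, with 1, 2 and 2 peak lists. FOXA2 was mapped in endoderm after 5 days of Activin A and WNT3A, with 2 peak lists, and its bound DNA was also bisulfite sequenced (ChIP-bisulfite) in 2 libraries. The last group is 1 polyA RNA table of hepatoblasts, the cells reached after 5 further days in FGF2 and BMP4 (day 10), and it pools 2 replicates. The labels do not say whether the replicates of a group were separate cultures, so they may be technical. The binomial and counting intervals below cover counting error only.

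The FOXA2 lists held 43109 and 54053 peaks on the 24 chromosomes, the POU5F1 list 22460, the SOX2 lists 9165 and 9214, and the NANOG lists 29435 and 28270. Bisulfite library 1 listed 4013937 CpGs with 5209715 reads, and library 2 listed 3206259 CpGs with 4397839 reads. Median coverage was 1 read per CpG in both, and 57918 and 46898 CpGs had at least 5 reads. These read totals and the read counts of peaks below are sums over CpGs. A read that covers several CpGs is counted at each of them. Of 22238 genes on the 24 chromosomes in the hepatoblast table, 12299 (55.3%) had at least 1 FPKM and 4448 were listed at 0. The sequencing depth behind the peak lists and the RNA table is not given by the files and is unknown.

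The first question was how far the 2 lists of a factor describe the same sites. By share of overlapping peaks NANOG had the closest lists, with 72.0% of replicate 1 peaks overlapping a replicate 2 peak (95% exact binomial interval 71.5 to 72.5), 40.02-fold over circularly shifted lists. FOXA2 had 58.8% of replicate 1 peaks (58.3 to 59.3) and 47.5% of replicate 2 peaks, 15.2-fold over shifts, and SOX2 had 53.7% (52.7 to 54.7), 114-fold over shifts. The folds depended on the setting, from 59.9 with local shifts to 282 with reciprocal overlap of 50% for SOX2, from 7.02 among the top 5000 peaks to 45.6 with reciprocal overlap for FOXA2, and from 36.1 with local shifts to 189 among the top 5000 peaks for NANOG. None of 1000 shifted lists reached any of these overlaps (one-sided shift permutation p = 0.001, the smallest possible). Across overlapping pairs of peaks, Spearman's rho of the peak scores, which are the authors' own, was 0.79 for NANOG, 0.52 for FOXA2 and 0.50 for SOX2 (permutation p = 0.0001 each, the smallest possible, over peaks, which are not independent replicates). POU5F1 had 1 list, so its peaks have no replicate check.

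The FOXA2 lists differed in where their peaks lay. In replicate 2, 14436 peaks (26.7%, interval 26.3 to 27.1) were within 1 kb of an end of a gene locus of the RNA table (a locus edge), against 2153 (4.99%, 4.79 to 5.20) in replicate 1. Shifted lists gave 4.06% and 3.46%. POU5F1 peaks lay at locus edges in 16.7%, and SOX2 and NANOG peaks in 3.94 to 5.89%. The 28359 FOXA2 peaks called in replicate 2 alone had a higher median score than the replicate 2 peaks shared with replicate 1 (331 against 250), and 44.0% of them were at locus edges. Peaks called in replicate 1 alone had a lower median score than shared ones (80.9 against 157), and 1.77% were at locus edges. Among the 5000 highest scores of each FOXA2 list, 5.02% of replicate 1 peaks overlapped a replicate 2 peak, and 4771 replicate 2 peaks against 22 replicate 1 peaks had a score of 3100 or more, near the highest in any list. ACTB, GAPDH and the other 8 housekeeping genes all had a replicate 2 peak within 10 kb, and 2 of the 10 had a replicate 1 peak, but the share of the other genes with a peak rose as well, to 85.5% from 51.0%. The comparisons below rest on the 25201 FOXA2 consensus peaks, merged from peaks found in both lists, of which 7.87% were at locus edges.

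**Figure D1:**
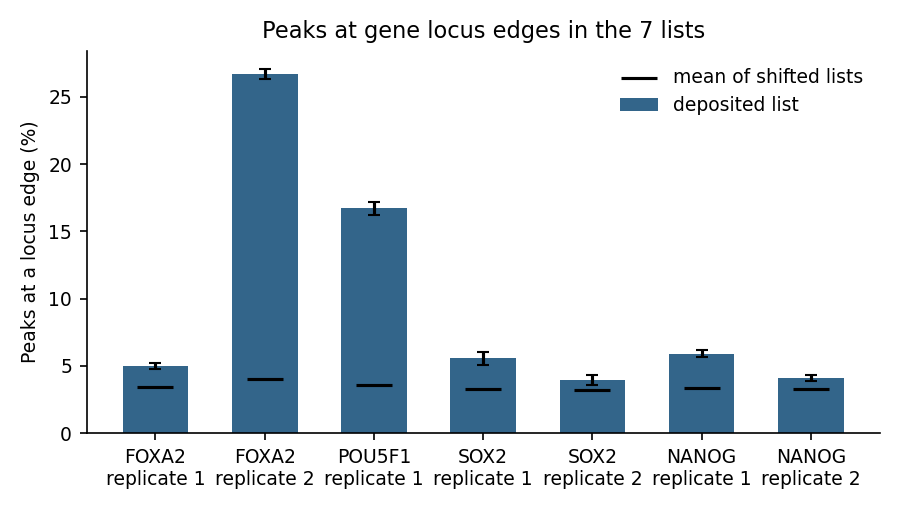
Bars give the share of peaks (%) within 1 kb of an end of a gene locus in each of the 7 deposited peak lists, with 95% exact binomial intervals, and black lines the mean of shifted lists. FOXA2 replicate 2 stands at 26.7% and POU5F1 at 16.7%, and the other lists lie between 3.94 and 5.89%.

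The hESC comparison asked how far POU5F1, SOX2 and NANOG occupy the same sites. Of 4793 SOX2 consensus peaks, 85.9% (84.9 to 86.9) overlapped a NANOG peak and 77.3% (76.1 to 78.5) a POU5F1 peak, 57.6-fold and 52.0-fold over shifts. Among POU5F1 peaks, 42.8% (42.2 to 43.5) overlapped NANOG, 28.8-fold over shifts, and 16.5% (15.98 to 16.95) overlapped SOX2, a share of 25.97% without SOX2 replicate 1 and 22.95% without replicate 2. The 3 factors met at 3388 POU5F1 peaks (15.1%), while 12537 POU5F1 peaks (55.8%) overlapped neither SOX2 nor NANOG. Each pairwise overlap exceeded all 1000 shifts (one-sided shift permutation p = 0.001 before and after Benjamini-Hochberg adjustment over 6 pairs, the smallest possible). The 10 shared peaks with the highest mean rank lay in or nearest to REST, ARHGEF38, PIM1, ETV6, PPP1R3B, CDX2, FBRS, MAP3K7, FLT3 and ARL15. The first of them, at an end of the REST locus (chromosome 4, 57772975 to 57774951), scored 3210.5 for POU5F1 and 1436.2 for SOX2. The peaks in REST and CDX2 and those nearest to FBRS (6417 bp away), PPP1R3B (113114 bp) and MAP3K7 (710982 bp) also overlapped a FOXA2 peak in endoderm.

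The next comparison set FOXA2 binding in endoderm beside earlier binding in hESC. NANOG peaks overlapped 13.2% of FOXA2 peaks (12.8 to 13.6), POU5F1 peaks 9.61% (9.25 to 9.98) and SOX2 peaks 3.04% (2.83 to 3.26), at 7.92-fold, 5.74-fold and 8.52-fold over shifts. The SOX2 share was 4.91% without SOX2 replicate 1 and 4.70% without replicate 2. None of 1000 shifts reached any of the 3 overlaps (one-sided shift permutation p = 0.001, the smallest possible). At least 1 of the 3 hESC factors overlapped 4295 FOXA2 peaks (17.0%, 16.58 to 17.51), and all 3 overlapped 609 (2.42%, 2.23 to 2.61). The POU5F1 overlap differed by position: 35.4% (33.3 to 37.5) of the 1984 FOXA2 peaks at locus edges and 7.41% (7.08 to 7.75) of the others, a split in which POU5F1 has 1 list. NANOG peaks overlapped 14.6% (13.1 to 16.3) of FOXA2 peaks at locus edges and 13.1% (12.6 to 13.5) of the others. Leaving out regions covered by a peak in all 7 lists lowered the SOX2 fold to 2.37, and the NANOG and POU5F1 folds to 6.91 and 4.61. Such regions are overlaps of FOXA2 with all 3 factors by definition, so their removal had to lower each fold.

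**Figure D2:**
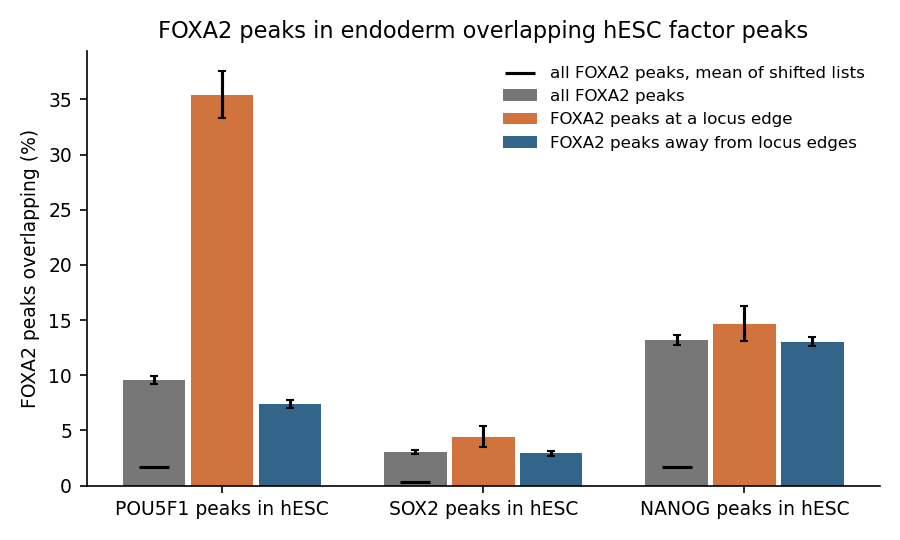
Bars give the share of FOXA2 consensus peaks (%) that overlap a POU5F1, SOX2 or NANOG peak from hESC, for all peaks and for peaks at and away from locus edges, with 95% exact binomial intervals, and black lines the mean of 1000 shifted lists. POU5F1 overlap reaches 35.4% at locus edges against 7.41% elsewhere, and NANOG overlap is 14.6% and 13.1%.

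Gene lists fixed before the data were examined showed which genes carried peaks within 10 kb of their locus. FOXA2 peaks lay at 15 of 18 definitive endoderm genes, among them FOXA2 itself with 4 peaks, GATA4 with 4 and EOMES, GSC and PRDM1 with 3 each, and at 17 of 18 WNT, NODAL, BMP and FGF signalling genes, the exception being DKK4. HHEX, KIT and FZD8 were the endoderm genes without a FOXA2 consensus peak. HHEX and KIT had peaks in each list that did not overlap between the lists, and FZD8 had a peak in replicate 2 alone. The shares were 83.3% and 94.4% against 41.3% of the other genes (two-sided Fisher's exact test, adjusted p = 0.0022 and 6.6e-05 over 60 tests of 15 lists and 4 factors). The trophoblast list had 9 of 10 genes with a FOXA2 peak (Fisher's exact adjusted p = 0.0089), and HAND1 was the exception, but all 7 alternatives lost this call (exact adjusted p from 0.059 to 0.78). The hepatoblast and hepatocyte list had 16 of 24, including HNF4A with 5 peaks and AFP, APOA1, APOA2 and TTR, but not ALB (66.7% against 41.3%, Fisher's exact p = 0.020, adjusted p = 0.061). This list passed by nearest locus (exact adjusted p = 0.0057) and at a score of at least 100 (exact adjusted p = 0.0073). ALB had a FOXA2 peak in replicate 1 alone. At 11 of 20 pluripotency genes a FOXA2 peak was present, with SOX2 carrying 3 and POU5F1 and NANOG none (Fisher's exact adjusted p = 0.50). The SOX2 locus used here spans 130.9 kb, against 6.34 kb for POU5F1 and 6.66 kb for NANOG, both with a peak in replicate 2 alone. The 3 FOXA2 enrichments that passed depended on the peak list and the distance. From replicate 2 alone, where 85.5% of the other genes had a peak, 0 of 15 lists passed, and from replicate 1 alone 2 passed. With peaks inside the locus the signalling list passed (Fisher's exact adjusted p = 0.0069) and the definitive endoderm list did not (0.36). With peaks within 50 kb and with the union of both lists 0 passed, so definitive endoderm lost its call there too.

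No other list passed the test for FOXA2. FOXA2-bound genes had long loci, however (median 56.8 kb against 15.5 for the others), and against random lists matched on locus length 6 lists lay above the central 95%: hepatoblast and hepatocyte at percentile 99.98, epithelium at 99.3, pluripotency at 98.3, and the 3 lists that passed at 99.96 or more. A peak was present at 4 of 10 pancreas, 3 of 8 intestine, 3 of 7 lung and thyroid, 7 of 18 mesoderm and heart, 6 of 15 ectoderm and neural and 3 of 10 fibroblast and mesenchyme genes. The shares were 5 of 10 for endothelium and blood, 6 of 8 for epithelium, 5 of 9 for DNA methylation machinery and 2 of 10 for housekeeping genes. In hESC, Fisher's exact test with Benjamini-Hochberg adjustment found POU5F1 peaks enriched at 7 lists, SOX2 peaks at 3 and NANOG peaks at 5. Against length-matched lists SOX2 peaks were also above the central 95% at definitive endoderm (percentile 99.91), trophoblast (99.67) and hepatoblast and hepatocyte genes (98.28). NANOG peaks were so at mesoderm and heart (99.98) and trophoblast genes (98.88), and POU5F1 peaks at no further list. Pluripotency genes had a NANOG peak in 18 of 20 (Fisher's exact adjusted p = 2.2e-06), a SOX2 peak in 13 (adjusted p = 7.6e-07) and a POU5F1 peak in 17 (adjusted p = 0.0022). Definitive endoderm genes already carried a POU5F1 peak in hESC in 16 of 18 (Fisher's exact adjusted p = 0.0017) and a NANOG peak in 14 (adjusted p = 0.00097). POU5F1 peaks were also enriched at the pancreas list (10 of 10 genes), the ectoderm and neural list (14 of 15), the mesoderm and heart list (15 of 18), the fibroblast and mesenchyme list (9 of 10) and the signalling list (16 of 18). SOX2 and NANOG peaks were both enriched at the ectoderm and neural list (7 and 12 of 15 genes) and the signalling list (6 and 13 of 18), and NANOG peaks at the pancreas list (7 of 10). With peaks inside the locus the signalling list lost its call for all 3 factors (exact adjusted p = 0.95 for POU5F1, 0.88 for SOX2 and 0.70 for NANOG), and for SOX2 also with the union of lists (exact adjusted p = 0.39) and at a score of at least 100 (0.43). With peaks within 50 kb, 1 list passed for POU5F1 and 2 for NANOG, and with peaks inside the locus 3 passed for NANOG. At a score of at least 100, 20% of fibroblast and mesenchyme genes had a POU5F1 peak, a share below that of the other genes.

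The ChIP-bisulfite comparison asked how methylated the DNA bound by FOXA2 is. Each library carries the same sample number as the FOXA2 list of its replicate. At EOMES, GATA6 and FOXA2 the strongest FOXA2 peaks were nearly free of methylation: 1 of 170 and 1 of 105 reads methylated at EOMES in libraries 1 and 2, 1 of 284 and 3 of 186 at GATA6, and 0 of 131 and 0 of 61 at FOXA2. The FOXA2 peak lay at chromosome 20, 22557687 to 22560913, and its 0 counts allow levels of up to 2.78% and 5.87% (exact binomial). Intervals for single peaks take each read at each CpG as independent. Neighbouring CpGs can share a read, so these intervals are likely too narrow. The strongest CXCR4 peak had 11.4% (interval 5.07 to 21.3, 70 reads) and 25.0% (13.6 to 39.6, 48 reads), and that of HNF4A 24.4% (12.4 to 40.3, 41 reads) and 23.8% (8.22 to 47.2, 21 reads). TTR, a liver gene, had 1 of 1 and 4 of 4 reads methylated at its peak, which leaves the level open. Methylation was lower inside FOXA2 peaks in library 1, with a mean of 34.1% against 58.6% in flanks 1 to 5 kb away. This rested on 41 peaks with at least 3 CpGs at 5 reads or more on both sides (median difference -20.9 points, two-sided sign-flip permutation p = 1e-05, the smallest possible). In library 2 the means were 26.1% and 58.3% over 8 peaks (median difference -32.4 points, exact two-sided sign-flip p = 0.023). With the union of both FOXA2 lists the median difference was -6.21 points in library 1 (59 peaks lower inside, 35 higher) and -20.8 in library 2. Over the libraries the median difference was -26.6 ± 8.18 points (SD, n = 2), with no test over the 2 libraries. Reads inside peaks come mainly from bound fragments and flank reads from background, and no bisulfite library of unselected DNA was among the samples. The comparison therefore cannot tell a lower level of the region from a lower level of the bound molecules.

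Because few peaks met that coverage, reads were also pooled per peak, a choice made after the coverage was seen. With at least 10 reads inside and in the flanks, 4174 of 4706 FOXA2 peaks were lower inside in library 1 (means 26.8% and 59.3%, median difference -33.9 points) and 1670 of 1985 in library 2 (21.8% and 50.5%, -30 points). Both gave permutation p = 1e-05, two-sided, the smallest possible. The median difference was -52.4 and -48.3 points at locus edges and -29.1 and -23.2 points away from them. By distance from the peak centre, CpGs with at least 5 reads averaged 24.7% within 100 bp and 40.1% at 2500 to 5000 bp in library 1, and 18.5% and 29.3% in library 2. In library 2 the lowest level, 9.64%, lay at 250 to 500 bp. Every bin held at least 836 CpGs. Unlike the flanks, the bins keep CpGs that lie inside other FOXA2 peaks, and a CpG near several peaks is counted for each. The farthest bin is therefore not a level outside FOXA2 peaks. The difference between the nearest and the farthest bin depended on coverage: it was -15.4 points in library 1 but -3.02 at 10 reads or more, and -10.8 points in library 2 but -3.69 at 3 reads or more.

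**Figure D3:**
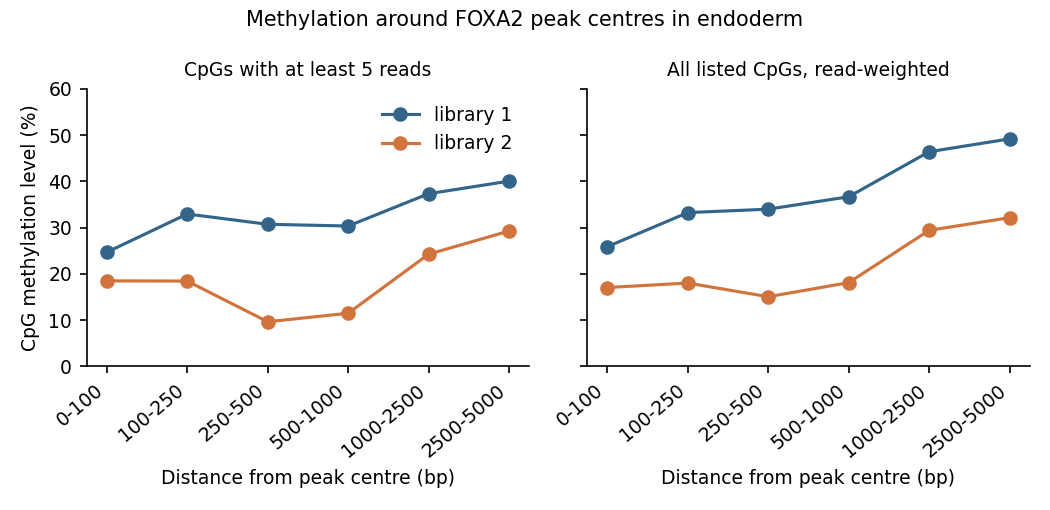
Points give the CpG methylation level (%) in 6 bins of distance (bp) from the centre of FOXA2 consensus peaks for bisulfite libraries 1 and 2, for CpGs with at least 5 reads (left) and for all listed CpGs weighted by reads (right). Levels within 100 bp, 24.7% and 18.5% on the left, lie below those at 2500 to 5000 bp, 40.1% and 29.3%. The bins keep CpGs that lie inside other FOXA2 peaks.

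FOXA2 peaks that met the coverage limit were seldom fully methylated. Of the 25201 consensus peaks, 429 had at least 3 CpGs at 5 reads or more in both libraries. This limit favours peaks with many CpGs or many reads, so the shares describe these peaks only. Among the 429, 142 (33.1%, interval 28.7 to 37.8) in library 1 and 212 (49.4%, 44.6 to 54.3) in library 2 had a mean level below 20%. Levels above 80% were found at 3 and 5 peaks. The class was the same in both libraries for 329 peaks (76.7%), and levels correlated across peaks (Pearson's r 0.72, Spearman's rho 0.69, across peaks, which are not independent replicates). When each library was read on the FOXA2 list of its own number, low methylation covered 40.5% of 1463 peaks in library 1 and 84.4% of 1881 peaks in library 2. With pooled reads, 91.3% and 95.3% of 1501 peaks at locus edges were low, against 31.5% and 36.1% of 3550 peaks away from them. At 10 reads per CpG the low share in library 1 was 53.85%, and with a limit of 10% it was 31.5% in library 2.

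Among the 10 FOXA2 peaks with the highest mean score, the one inside the CDH15 locus (chromosome 16, 89251671 to 89254159) was methylated, with 987 of 1184 reads in library 1 (83.4%) and 296 of 366 in library 2 (80.9%). The CDH15 read counts were far above the medians of 23 and 31 reads per peak in libraries 1 and 2 with pooled reads. The level at CDH15 may therefore not describe a single site. The peak nearest to KCNAB2 also had a high level (68.4% of 98 and 68.1% of 72 reads). Those nearest to SEMA3D (6.94% of 72 and 8.11% of 37 reads), LOC145837 (5.81% of 155 and 7.14% of 84) and inside NTN1 (8.14% of 86 and 4.35% of 23) were low. The others lay nearest to or inside C14orf145, ROBO2, TAG, GPR65 and TANC1, and none of the 10 was at a locus edge. ROBO2 (41.2% of 131 and 23.6% of 72 reads) and GPR65 (22.9% of 35 and 25% of 16) were intermediate. C14orf145 (14.6% of 41 and 0% of 10) and TAG (0% of 12 and 0% of 6) were lower, and TANC1 had 10 and 2 reads. Only 8 peaks had at least 5 CpGs with 10 reads or more in both libraries. After CDH15 they were LOC285696 (37.1% and 32.4%), ADARB2 (2.92% and 1.41%) and 5 peaks on chromosome 7 at or near NCF1C, GATSL1, GATS, GTF2IP1 and GATSL2, each below 2.2% in both libraries. Several of these chromosome 7 loci are near-identical copies, so reads assigned to any 1 of them are uncertain.

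FOXA2 peaks with a higher mean score of both lists were less methylated. With pooled reads this held for replicate 2 scores with library 2 but not for replicate 1 scores with library 1. Spearman's rho of the mean score and mean level was -0.55 over 429 peaks (two-sided permutation p = 1e-05, the smallest possible, adjusted p = 0.00011 over 17 relations), and -0.55, -0.37 and -0.63 within tertiles of covered CpGs per kb, 143 peaks each. Over the same 429 peaks, rho was -0.47 for replicate 1 scores with library 1 and -0.53 for replicate 2 scores with library 2 (permutation p = 0.0001 each, the smallest possible). With pooled reads over 5051 peaks the pairings parted, at 0.068 and -0.62. Of the 5000 highest scores, 85.9% in replicate 2 and 4.04% in replicate 1 lay at locus edges. The relation was not computed apart for peaks at and away from locus edges. At 10 reads per CpG, 13 peaks gave -0.034 (permutation p = 0.92). Peaks are not independent replicates, so these values describe the 2 samples.

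FOXA2 peaks that overlapped a POU5F1, SOX2 or NANOG peak from hESC were less methylated in endoderm than FOXA2-only peaks. In library 1 the means were 12.8% over 267 shared peaks and 29.0% over 1107 others (difference -16.2 points), and in library 2 they were 5.10% over 211 and 19.7% over 423 (-14.6 points). The 2 two-sided permutation tests gave p = 1e-05, the smallest possible, and adjusted p = 0.0001. POU5F1, SOX2 and NANOG taken alone each gave a lower level, from -11.2 to -23.4 points. The difference was below 0 in every tertile of covered CpGs per kb in both libraries, from -6.31 to -21.4 points. Away from locus edges, with pooled reads, it was -15.1 points in library 1 and -12.2 in library 2. Read on the FOXA2 list of its own number, library 2 gave -4.37 points, and at 10 reads per CpG it gave -21.5 points over 14 peaks (permutation p = 0.11).

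POU5F1, SOX2 and NANOG peaks outside all FOXA2 peaks showed no difference from their flanks that passed the test at 5 reads per CpG. Between 6 and 22 peaks entered each test, with median differences of 4.22 and 8.60 points for POU5F1, 7.32 and -2.97 for SOX2 and 0.43 and -18.0 for NANOG in libraries 1 and 2 (two-sided sign-flip permutation p = 0.19 to 1, exact where at most 12 peaks entered). Pooled reads, with 124 to 420 peaks, gave lower levels inside POU5F1 peaks (-17.4 and -4.02 points, sign-flip permutation p = 1e-05, the smallest possible, and 0.00013) and NANOG peaks (-18.0 and -5.86 points, p = 1e-05 and 8e-05). SOX2 peaks gave -3.42 points in library 1 (permutation p = 0.00086) and 0.22 in library 2 (p = 0.64). These CpGs lie outside all FOXA2 peaks of either list, so their reads come mainly from background fragments.

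No single CpG was called different between the 2 bisulfite libraries. Of 27209 CpGs with at least 5 reads in both, 0 passed Fisher's exact test with Benjamini-Hochberg adjustment, and 582 had an unadjusted two-sided p below 0.05. At this coverage 41.5% of simulated changes from 5% to 95% were called, so the result does not show that the libraries agree. On the same 101732 CpGs inside FOXA2 consensus peaks, the mean level was 20.3% in library 1 and 17.8% in library 2. Over all reads in consensus peaks the levels were 27.6% and 13.2%, and outside all FOXA2 peaks 60.3% and 53.5%.

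The RNA comparison asked what became of FOXA2-bound genes in hepatoblasts. The FOXA2-bound genes with the highest levels were TMSB10 (7893 FPKM), RPS27 (5097), KRT18 (4469), RPLP1 (4407) and RPL41 (3702), followed by ACTG1, TMSL3, MDK, RPS28 and RPL29 (3399 to 2388 FPKM). The FPKM of 4 of these 10 genes lay above their own deposited intervals, so their levels are uncertain: TMSB10 (3681 to 7328), RPS27 (1830 to 3565), RPS28 (1037 to 2011) and TMSL3 (3066 against 6.45 to 14.2, in a locus of 1475 kb). The 9200 genes with a FOXA2 peak within 10 kb had a median of 2.88 FPKM against 1.23 for the 13038 others, and 60.8% (59.8 to 61.8) against 51.4% (50.6 to 52.3) reached 1 FPKM. Their median log2(FPKM + 1) was 0.25 above that of random lists matched on locus length, above all 10000 lists. This excess was 0.49 without FOXA2 replicate 1, 0.15 without replicate 2 and 0.08 among genes of at least 0.1 FPKM (percentile 99.98). The 2749 genes bound by FOXA2 without a hESC factor peak did not stand apart (-0.03, percentile 32.7). The 6451 genes bound by both (0.36) and the 5248 with a hESC factor peak only (0.28) exceeded all 10000 lists, and genes with a POU5F1 peak did so by 0.43. Genes with a SOX2 peak were 0.24 above matched lists (percentile 99.9), and genes with a NANOG peak 0.03 above them (percentile 78.5). The 5 genes with most FOXA2 peaks lay in 3 very long loci: NRXN3 (22 peaks), FLRT3 and MACROD2 (21, the same locus), and CNTNAP2 and MIR548F3 (20, the same locus). FLRT3 had 27.6 FPKM, CNTNAP2 25.5 and NRXN3 0.92.

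Genes beside weakly methylated FOXA2 peaks had higher levels in hepatoblasts than genes beside peaks of intermediate methylation, at 5 reads per CpG and with pooled reads. The 133 genes with a mean peak level below 20% had a median of 3.85 FPKM (percentile 99.8 of random lists of FOXA2-bound genes with measured methylation), and the 139 genes at 20 to 80% had 1.17 (percentile 0.93). At 10 reads per CpG the low class held 10 genes with a median of 0.15 FPKM (percentile 31.5). With pooled reads the medians were 5.95 over 2817 genes and 1.23 over 1164, and away from locus edges 3.02 over 792 and 1.14 over 1067. Genes beside peaks above 80% were too few to rank at 5 reads per CpG. With pooled reads their medians were 5.50 over 6 genes and 7.38 over 9 away from locus edges (percentiles 58.6 and 88.5), few genes in both. The hepatoblast table is 1 pooled sample, so no p-value was computed across genes.

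Marker lists described the state of the hepatoblast sample. APOA1 (193 FPKM, deposited interval 120 to 230) and APOA2 (148, 68.2 to 148) led the hepatoblast and hepatocyte list, with TBX3 at 46.7, DLK1 at 37.2, TTR at 16.2, ALB at 14.3, AFP at 5.17 and HNF4A at 3.32. The list's median was 1.03 FPKM with 14 of 24 genes at 1 or more (percentile 31.1 among random lists). Several mesoderm genes were high: ACTC1 had 1855 FPKM, HAND1 997, MSX1 256 and MSX2 214. The mesoderm and heart list had a median of 14.3 with 14 of 18 genes at 1 or more (percentile 99.3). The others were T at 0.18, MESP1 at 0.16, TBX5 at 0.090 and MYH6 at 0.085. The fibroblast and mesenchyme list had a median of 91.2 with 10 of 10 genes at 1 FPKM or more (percentile 100), led by VIM at 3841, COL1A1 at 986, COL3A1 at 515 and COL1A2 at 509, with DCN at 2.83. The epithelium list had a median of 78.1 (KRT8 5852, KRT18 4469, KRT19 1282, EPCAM 106), the trophoblast list 20.2 (TFAP2A 68.6, GATA3 65.4, KRT7 41.9, CDX2 29.0, and CGA 0.30), and the signalling list 14.4 (ID1 401, BMP4 172). With the housekeeping list (median 314), 6 of 15 lists lay above the central 95% of random lists, and 0 lay below it. The trophoblast list shares HAND1 with the mesoderm list and was at percentile 92.9 without it (9 genes, a test chosen after the result was seen), and the mesoderm and heart list fell to 92.2 among genes of at least 0.1 FPKM.

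The remaining lists lay within the range of random lists. Pluripotency genes had a median of 3.18 FPKM (percentile 69.6), with LIN28A at 97.7 and POU5F1 at 40.5 (29.6 to 51.4) but NANOG at 0.25 (0.098 to 0.39). Definitive endoderm genes had a median of 3.28 (percentile 66.2), with CLDN6 at 360, GATA4 at 32.0, GATA6 at 17.1, SOX17 at 9.82 and FOXA2 at 7.18. The medians were 14.1 for DNA methylation machinery (percentile 95.3), 2.27 for ectoderm and neural genes (54.95) and 1.12 for intestine (36.4). They were 0.068 for endothelium and blood (5.57), 0.041 for lung and thyroid (9.03) and 0.027 for pancreas (2.75). Without genes below 0.1 FPKM, the mesoderm and heart list was at percentile 92.2, the signalling list at 93.8, the lung and thyroid list at 0.69 and the hepatoblast and hepatocyte list at 0.040. With a pseudocount of 0.1 the pancreas list was at 2.37.

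**Figure D4:**
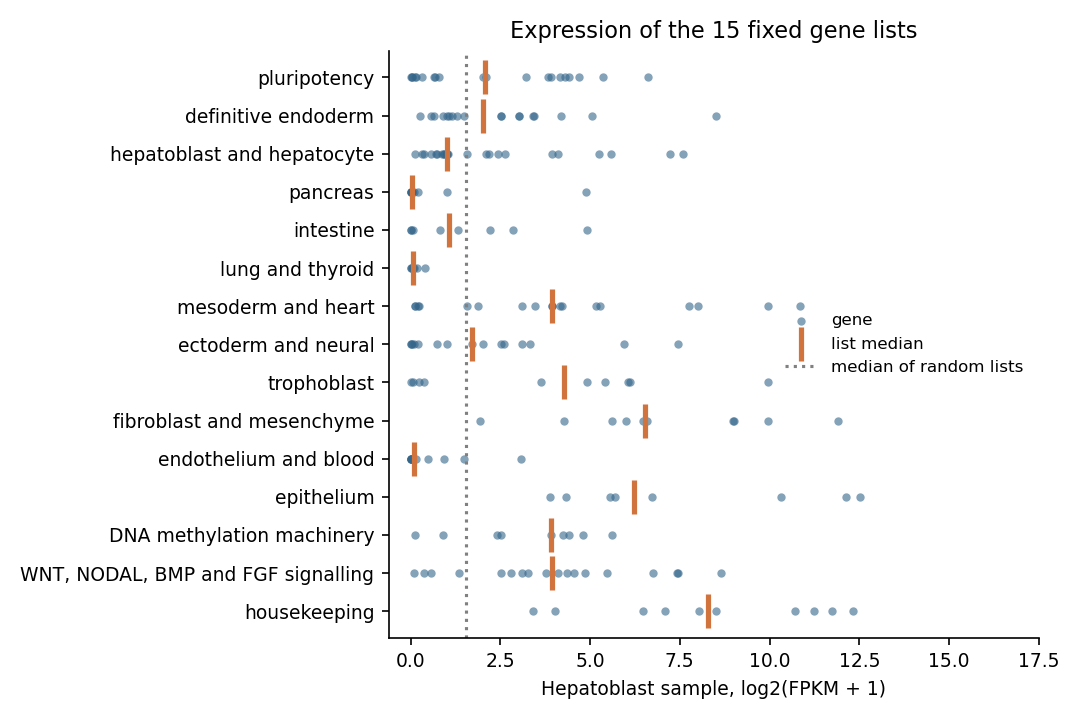
Each point is a gene of 1 of the 15 fixed lists at its log2(FPKM + 1) in the pooled hepatoblast sample, orange marks are list medians, and the dotted line is the median of random lists. The fibroblast and mesenchyme, epithelium and housekeeping lists have the highest medians (91.2, 78.1 and 314 FPKM), and the pancreas list the lowest (0.027 FPKM).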

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

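The values in this part are counts of peaks that enter no comparison, and no test of them was run. The deposited peak lists hold peaks on contigs outside the 24 chromosomes, which the report leaves out. FOXA2 replicate 1 has 33 and replicate 2 has 118, POU5F1 has 17, SOX2 replicate 1 has 106 and replicate 2 has 49, and NANOG replicate 1 has 41 and replicate 2 has 54. Each number is above the limit of 3 that a count of 0 allows. No control sample was used here to set them against, and no explanation for them was tested.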

How the results depend on the processing

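The alternatives with pooled reads, with peaks at or away from locus edges and without chromosome 1 were chosen after seeing the data, and the rest before. Of 267 alternatives to 38 results, 214 kept the direction and the side of the threshold or stayed within the error, and the 65 alternatives for peak overlap all stayed above shifted lists. Reciprocal overlap of 50% gave the highest fold for each pair of factors: 137 for SOX2 and NANOG, 134 for POU5F1 and SOX2, 70.7 for POU5F1 and NANOG, and 17.6, 15.4 and 10.2 for FOXA2 with SOX2, NANOG and POU5F1. The lower level inside FOXA2 peaks than in flanks held in all 15 alternatives in library 1 (-6.21 points with the union of lists to -52.4 at locus edges) and in the 13 with at least 6 peaks in library 2 (-20.8 to -53.9). Too few were left in library 2 at a score of at least 100 (3 peaks, -43.85 points) and with at least 5 CpGs (2 peaks, 1 of them higher inside, -5.74 points). Where a value below changed, the cause was not tested unless it is named.

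Replicate overlap moved with the peaks compared. At a score of at least 100 it was 70.02% for FOXA2, 43.6% for SOX2 and 77.0% for NANOG, and with reciprocal overlap of 50% it was 48.7%, 48.7% and 70.6%. With equal numbers of top peaks it was 51.1% for FOXA2 and 73.7% for NANOG, and among the 5000 top scores 5.02% for FOXA2, 51.0% for SOX2 and 81.5% for NANOG.

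Methylation values moved with coverage. The level within 100 bp minus that at 2500 to 5000 bp was -3.02 points in library 1 at 10 reads and -23.3 with pooled reads, and in library 2 it was -3.69 at 3 reads, -26.4 at 10 and -15.1 pooled. The share of low peaks in library 1 was 48.1% at 3 reads, 53.85% at 10 reads, 48.0% with limits of 30% and 70% and 49.3% pooled. In library 2 it was 31.5% with limits of 10% and 90% and 73.2% with 30% and 70%, limits that also moved the share of peaks in the same class to 90.7% and 62.7%. At 10 reads the relation of score and level lost its call (rho -0.034, 13 peaks), as did the difference of shared and FOXA2-only peaks in library 2 (-21.5 points, 14 peaks), both with few peaks left. For replicate 1 scores with library 1, pooled reads turned rho to 0.068.

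At hESC factor peaks outside FOXA2 peaks the direction changed with the setting, except for NANOG in library 2, which stayed below the flanks. Pooled reads gave -17.4 and -4.02 points for POU5F1 in libraries 1 and 2, -3.42 and 0.22 for SOX2, and -18.0 and -5.86 for NANOG. All of these but SOX2 in library 2 passed the threshold (sign-flip permutation p from 1e-05 to 0.00086), against none at 5 reads per CpG. At 3 reads the values were -0.93 for POU5F1 in library 2, 0.45 for SOX2 in library 2 and -5.48 for NANOG in library 1, and read-weighted levels gave -0.91 for POU5F1 in library 2 and -1.78 for NANOG in library 1.

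The share of FOXA2-bound genes at 1 FPKM or more was 62.6% with peaks inside the locus, 58.2% within 50 kb, 59.7% by nearest locus, 62.4% with the union of lists and 80.8% among genes of at least 0.1 FPKM, a filter that removes low genes. Leaving out either FOXA2 list gave 59.7 to 63.7%. The number of lists enriched for FOXA2 peaks was 1 with peaks inside the locus, 0 within 50 kb, 0 with the union and 0 to 2 when either list was left out. It was 1 for POU5F1 within 50 kb, and for NANOG 3 inside the locus and 2 within 50 kb. POU5F1 peaks at fibroblast and mesenchyme genes, enriched in the report, fell below the other genes at a score of at least 100 (20%). For single lists, 30 of 126 alternatives lost the call and 5 moved.

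With the replicate number as a block, only FOXA2 lists and bisulfite libraries are paired by their deposited sample numbers. Reading each library on its own list gave -17.65 and -21.4 points inside against flanks (pooled -30.3 and -43.0), low shares of 40.5% and 84.4%, and shared minus FOXA2-only levels of -16.4 and -4.37 points. SOX2 and NANOG lists share only a number, and their paired overlap was 41.9-fold and 48.7-fold over shifts. At 5 reads per CpG the block ended no call, and with pooled reads it turned the rho of score and level for number 1, as given above.

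Not run were a distance from peak summits, a sum of FPKM per symbol, since no symbol repeats, peaks against flanks at 10 reads, which left fewer than 6 peaks, and the low minus intermediate difference in expression at 10 reads, where the intermediate class held 2 genes and the 10 low genes were at percentile 31.5, unlike the low genes of the report. Depth limited every methylation value: at a median of 1 read per CpG, and of simulated changes from 5% to 95% at single CpGs with 5 reads in both libraries, 41.5% were called.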

Other observations

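The tests of replicate 2 scores, housekeeping genes, reads per CpG, locus edges, covered CpGs per kb with pooled reads and MYH6, and the CpG shares at the end, were chosen after the result was seen. The test within strata of the peak score was chosen after its pattern but before its values.

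FOXA2 peaks in endoderm lay at 11 of 20 pluripotency genes, 55% against 41.4% of the other genes, which did not pass the test (Fisher's exact adjusted p = 0.50), while random lists matched on locus length held 6.46 such genes on average (percentile 98.3). Among them, the strongest peaks at SOX2 (1 of 123 and 5 of 209 reads methylated in libraries 1 and 2), SALL4 (2 of 80 and 3 of 151) and FOXD3 (6 of 150 and 2 of 294) overlapped POU5F1 and NANOG peaks from hESC. Of the liver genes, the strongest AFP peak had 4 of 7 and 3 of 7 reads methylated and overlapped no hESC factor peak, while TBX3 had 2 of 180 and 1 of 89. These genes belong to the fixed lists, and the peaks shown were chosen after their values were seen.

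In hepatoblasts, genes of the signalling list included ID1 at 401 FPKM, ID2 at 170.2, FST at 107.7, LEF1 at 43.2 and AXIN2 at 19.35. Maintenance and de novo methyltransferases were present (DNMT1 48.1, DNMT3A 26.9, DNMT3B 20.5), as were TET1 at 4.68 and TET3 at 4.26, while DNMT3L had 0.089 FPKM. Of the pluripotency list, LIN28A (97.7), POU5F1 (40.5) and DPPA4 (25.0, interval 18.2 to 31.7) stood far above ZFP42 at 0.023 and FGF4, which was listed at 0. These are values of 1 pooled sample.

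The first pattern is the large share of FOXA2 replicate 2 peaks at locus edges. Deeper sequencing alone would add weak peaks, but peaks found in replicate 2 alone scored 1.33 times the shared ones at the median (95% bootstrap interval 1.26 to 1.41), which argues against it. A pull-down of promoter DNA whatever its factor may be the source and stays open: 10 of 10 housekeeping genes had a replicate 2 peak at a locus edge against 70.6% of the other genes (Fisher's exact p = 0.040, two-sided), but this window was tried after one of 10 kb, where even 10 of 10 could not pass (exact p = 0.38), and adjusted over both the exact p was 0.080. Bisulfite library 1 had 0.995 times the flank's reads per CpG inside these peaks and library 2 had 1.28 times. Since list and library of 1 number share a sample number, a difference between the cultures and a difference between the pull-downs cannot be told apart.

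The second pattern is the lower methylation of FOXA2 peaks shared with hESC factors. Position at locus edges is not the whole cause, since the smaller difference of the libraries away from edges was -12.2 points. Peaks away from edges may still include promoters inside loci, so promoter position itself stays open. Within tertiles of covered CpGs per kb the smallest of 6 differences was -6.48 points with pooled reads (-6.31 at 5 reads per CpG). Covered CpGs depend on read depth as well as on sequence, so CpG density itself stays open as a cause. Higher peak scores may be part of the cause. Within 10 equal strata of the replicate 2 score the pooled difference went from -16.9 to -10.05 points in library 1. In library 2 it went from -13.5 to -6.16. In the whole replicate 2 list, however, 4771 peaks scored 3100 or more, and the 5000 highest scores had a median of 3100. The top strata therefore may not separate peaks by score. In the lowest and middle tertile of the replicate 2 score, the pooled differences were -19.5 and -11.95 points in library 1. In library 2 they were -11.3 and -8.05 (two-sided permutation p = 0.0001 each, the smallest possible). These values argue against the replicate 2 score as the whole cause for the peaks of those tertiles, though scores still vary within a tertile. The replicate 1 score was lower in shared peaks (medians 185 against 195 and 152 against 169), and its strata left -16.8 and -13.3 points. That score therefore did not account for the difference. Each stratified permutation test gave p = 0.0001, two-sided, the smallest possible. A candidate explanation is that these regions were already unmethylated in hESC, where POU5F1, SOX2 or NANOG bound them. Methylation in hESC was not analysed here, so this stays a hypothesis.

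The third pattern is the level of mesoderm and mesenchyme transcripts in the hepatoblast sample. Heart muscle cells would bring MYH6, which had 0.0046% of the FPKM of ACTC1. TNNT2 had 17.6 FPKM, however, ISL1 35.1, HAND2 16.8 and NKX2-5 7.57, while TBX5 had 0.090. The test rests on 1 gene, so heart muscle cells stay open. Feeder fibroblasts and a mixed fate of the differentiating cells were not tested, and per the labels' protocols the feeders were mouse cells and the cells were moved to matrigel before differentiation.

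CpGs were unevenly spread in both bisulfite libraries. Chromosome 1 held 14.3% and 16.25% of the CpGs listed outside FOXA2 peaks, at a mean of 1.68 and 1.62 reads. Among CpGs with at least 10 reads, 42.2% and 44.7% lay in 5 windows of 1 Mb. Inside peaks of FOXA2 replicate 2 alone, the same 249271 CpGs averaged 6.04% methylation in library 1 and 4.53% in library 2.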
